A study of Pseudomonas syringae with 6 samples.

How the data were processed

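RNA-seq libraries of *Pseudomonas syringae* pv. tomato DC3000, wild type, were compared between King's B medium (3 libraries) and minimal medium (3 libraries). Per the labels' protocols, ribosomal RNA was removed from total RNA with a probe-based kit for Gram-negative bacteria, and libraries were made with a directional (strand-keeping) kit. The design text of the series describes 3 biological replicates per condition. Groups and replicate numbers were taken from the sample titles and media labels. The submitters' processing notes name FastQC 0.11.2, Bowtie2 2.3.1, TopHat2 2.1.1, SAMtools 0.1.19 and HTSeq 0.6.1, with no settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be separable.

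The deposited values are whole numbers, raw read counts per locus tag without normalization by the authors, in the layout that htseq-count writes, with 1 file per library. Each file holds 5842 locus tags and 5 rows that name no gene. Those 5 rows were left out of library sizes and tests. Reads outside annotated features made up 18.6, 8.34 and 6.13% of all rows in King's B replicates 1, 2 and 3 and 4.41, 26.9 and 6.56% in minimal medium replicates 1, 3 and 4. Ambiguous reads made up 0.18 to 1.60% and unaligned reads 1.37 to 3.66%. The row for reads with more than one alignment was 0 in each file, while copies of the same ribosomal RNA had nearly equal counts, so reads of repeated genes were placed among their copies in a way the files do not record; values of near-identical genes are uncertain.

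The values are read counts, but the format of the files (tab-separated text without a header under a comma-separated extension) could not be read by the unit check used in this work, so they were recorded there under the unit "other", which does not describe them. For that reason edgeR's quasi-likelihood test, fixed as the main test before the data were examined, was not run, and DESeq2, fixed as an alternative, was not run either. limma-voom, fixed beforehand as an alternative, was used as the main test instead, and the test against a fold change of 2 used limma's treat. The gene list test fixed beforehand, camera, was run on the voom values.

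Counts were tested in R 4.3.3 with limma 3.58.1. A tag was tested when at least 3 libraries reached the CPM that 10 reads make at the median library size and it had at least 15 reads in all, which left 4726 tags. Library sizes for this filter included reads on r tags. In libraries with many such reads the cut was therefore a larger share of the remaining reads. Scaling factors were TMM factors, computed with code written from the published method, with 30% of M values and 5% of A values trimmed. voom weights, a linear model with medium as the only term, and robust empirical Bayes moderation gave log2 fold changes of minimal medium over King's B, standard errors and two-sided p-values. The model had 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested tags, with a threshold of 0.05. CPM values were computed on TMM-scaled library sizes. The same code was tested on simulated counts for the comparison of minimal medium with King's B (5842 tags simulated, 5004 tested, 200 changed, dispersion 0.05). Among changed tags that were tested, it recovered 27.1% of 2-fold and 88.5% of 4-fold changes in the right direction, with median estimates of 0.97 and 2.03 in log2. Of its calls, 2.63% were false. The simulation changed few tags, equally up and down, and held no shift between libraries, while 54.8% of tested tags were called in the data. Its share of false calls therefore does not carry over to those calls. Recovery of 90% of the 4-fold changes had been set as a target and was missed.

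Before the data were examined, 34 gene lists were fixed. Of these, 29 were defined by gene symbols or products alone and could not be filled, because none of the 5842 tags matched the gene table at hand, which lists 5263 genes of another strain. The other 5 lists were defined by 101 locus tags from the published numbering of the DC3000 genome as known beforehand, 74 of which were tested; their membership was not checked against an annotation, and no individual gene names were assigned. No coordinates, lengths or GC content could be given for the same reason. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's members move one way without comparing them with other genes; p-values were adjusted over the 5 lists. Each list's median was also set against 10000 random lists matched on mean expression, made of single tags or of blocks of neighbouring tags. All 5 lists passed with the preset correlation and with fry, and 0 of 5 passed with an estimated correlation, where unadjusted p-values ranged from 0.027 for the effectors to 0.20 for the type III apparatus. The estimated correlation of the effectors was -0.011, below the preset 0.01. Their unadjusted camera p was still lower with the preset, at 0.0022. Correlation between members therefore does not alone account for the difference between the 2 forms of camera.

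The tags named in the text were chosen by a rule fixed beforehand. In each list it takes the 2 members with the smallest p in the list's main direction and the called member furthest in the other direction. Outside the lists it takes 2 tags that rose and 2 that fell the furthest, among those with an adjusted p below 0.05, libraries that do not overlap between media and at least 10 CPM in the higher medium. PSPTO_2606, PSPTO_1391, PSPTOA0012, PSPTO_4709 and PSPTO_4710 were named after their values were seen.

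Replicates were compared by a chi-square test of their counts over tags other than r and t tags with at least 20 reads per pair. Every pair within a medium differed by more than sampling noise, so all 6 libraries were counted separately. The closest pair was King's B replicates 2 and 3 (chi-square per degree of freedom 1.25). That test cannot tell separate cultures from repeat preparations of the same RNA, so the independence of the libraries rests on the design text. Alternatives fixed beforehand were median-of-ratios factors, scaling to total counts, no filter on low counts beyond removing tags without reads, a mean of at least 10 CPM, leaving out r and t tags, leaving out the 10 most abundant tags, the replicate number as a block, leaving out each library in turn, an adjusted p of 0.01, and the other list tests. Comparisons of single values between media used a two-sided exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.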

Results

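The transcriptome of wild-type *Pseudomonas syringae* pv. tomato DC3000, a bacterial pathogen of tomato and *Arabidopsis*, was measured by RNA-seq in cultures grown in King's B medium, a rich peptone and glycerol medium, and in minimal medium, a defined medium. Each medium was represented by 3 libraries described as biological replicates, numbered 1, 2 and 3 for King's B and 1, 3 and 4 for minimal medium. The series addresses how nutrition regulates pathogenesis genes, and the contrast between the media is the only one in the design. Reads were counted on 5842 locus tags, and between 497588 and 1172773 reads per library fell on them.

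Most of the reads in 3 of the 6 libraries came from the 15 tags with an r in their number, the form used for ribosomal RNA genes. These r tags held 0.480% of the reads on genes in King's B replicate 1 (95% exact binomial interval 0.463 to 0.499%), 37.9% in replicate 2 (37.8 to 38.0%) and 56.2% in replicate 3 (56.1 to 56.3%). In minimal medium they held 86.2% in replicate 1 (86.1 to 86.3%), 28.8% in replicate 3 (28.7 to 28.9%) and 86.1% in replicate 4 (86.1 to 86.2%). The intervals cover counting error only. The shares averaged 31.5 ± 28.4% in King's B and 67.0 ± 33.1% in minimal medium (SD, n = 3 each; two-sided exact permutation p = 0.3, where 3 libraries against 3 cannot give less than 0.1). Reads left for tags other than r and t tags numbered 564979, 630374 and 466501 in King's B replicates 1, 2 and 3, and 151765, 354090 and 162521 in minimal medium replicates 1, 3 and 4. Median counts over those tags were 30, 25 and 18 reads in King's B and 10, 31 and 14 reads in minimal medium, so that genes of low abundance were measured with few reads.

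**Figure D1:**
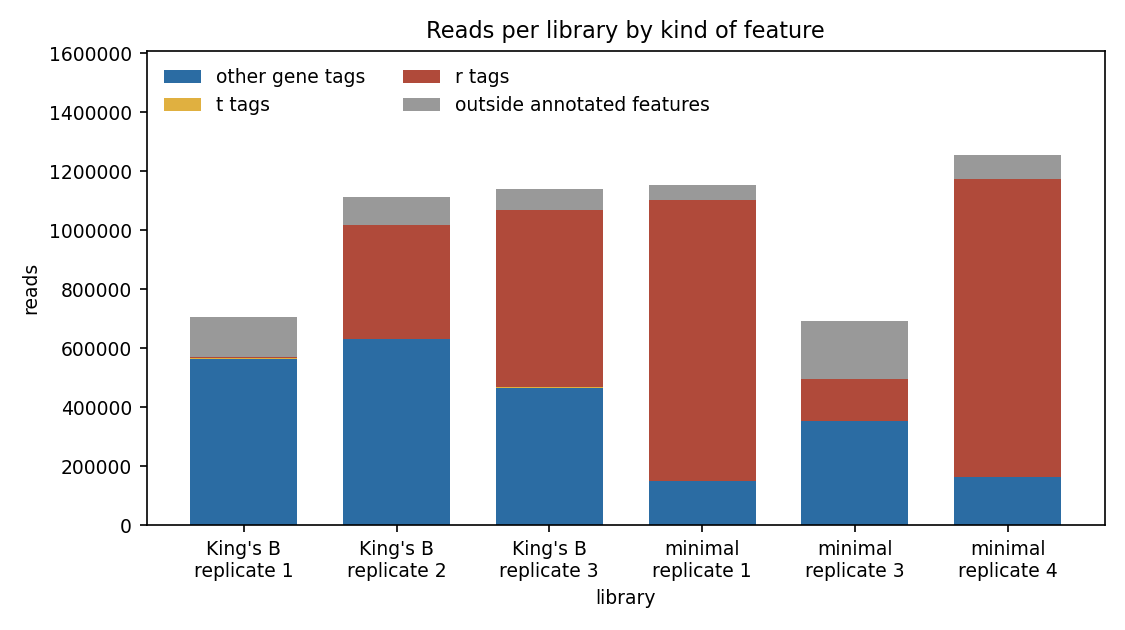
Reads per library, stacked by kind of feature, for 3 King's B and 3 minimal medium libraries (t tags: transfer RNA form; bars start at 0). Reads on r tags ranged from 2734 in King's B replicate 1 to 1010094 in minimal medium replicate 4, and reads on other gene tags from 151765 to 630374.

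The media differed across much of the genome. Of 4726 tags with enough reads to test, 2592 (54.8%) differed between media at an adjusted p below 0.05, of which 1325 were higher and 1267 lower in minimal medium. With a change of more than 2-fold required as well, 1837 tags remained, 912 higher and 925 lower. The yersiniabactin genes rose furthest of the 5 gene lists examined, with a median 14.6-fold rise, and the alginate genes fell by a median of 3.97-fold. Lists for the type III secretion apparatus, type III effectors and coronatine had median rises of 2.36-fold, 1.58-fold and 2.33-fold. The libraries of a medium did not overlap those of the other in 2295 of the 2592 changed tags and in 57.3% of all tested tags, where chance gives 10%. The test was limma-voom with trimmed-mean (TMM) scaling. Scaling to total counts alone, which includes the r tags, called 20 tags higher and 250 lower and moved the median log2 fold change of all tested tags from 0.02 to -0.79, so the share of higher tags among the calls was 51.1% with TMM and 7.41% without it. Within the lists it called 6 yersiniabactin tags higher, 5 alginate tags lower and 0 tags of the other 3 lists. Testing against a 2-fold change called 569 tags.

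Yersiniabactin, a siderophore that takes up iron, is assembled and transported by the products of a cluster of 12 listed tags, PSPTO_2595 to PSPTO_2606. All 12 tested tags rose in minimal medium, both over all genes and adjusted over the list alone (12 of 12). PSPTO_2602 rose from 104 ± 20.9 CPM (reads per scaled library size) in King's B to 2439 ± 807 CPM in minimal medium (SD, n = 3 each), a log2 fold change of 4.53 ± 0.24 (SE; limma-voom adjusted p = 4.5e-15). PSPTO_2605 rose 25.3-fold, from 31.7 ± 4.45 to 828 ± 248 CPM (log2 fold change 4.66 ± 0.25, limma-voom adjusted p = 4.5e-15). The smallest rise, 1.91-fold, was that of PSPTO_2606 at the end of the cluster (limma-voom adjusted p = 0.0076), and the other 11 tags had log2 fold changes of 3.19 or more. The list shifted upward against all other genes (camera adjusted p = 8.2e-12 with a preset correlation), and it had an adjusted p = 0.13 with an estimated correlation, which was 0.82 between its members.

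Alginate is an exopolysaccharide whose synthesis genes were listed as PSPTO_1232 to PSPTO_1243. All 12 tags were tested and all 12 fell in minimal medium, also when adjusted over the list alone. PSPTO_1243 fell from 1045 ± 87.0 CPM in King's B to 132 ± 30.3 CPM in minimal medium (SD, n = 3 each), which made it 7.98-fold higher in King's B (log2 fold change -3.00 ± 0.22, limma-voom adjusted p = 2.5e-12). PSPTO_1232, at the other end of the cluster, fell from 423 ± 29.8 to 101 ± 15.4 CPM (log2 fold change -2.07 ± 0.21, limma-voom adjusted p = 2.6e-09). The remaining 10 tags lay between -2.85 and -0.98. With quantile normalization the log2 fold changes of PSPTO_1243 and PSPTO_1232 were -1.60 and -0.9998. The list shifted downward (camera adjusted p = 9.3e-08) and had an adjusted p = 0.13 with an estimated correlation. Its median lay at percentile 0 among random lists of single tags matched on mean expression. Among random blocks of neighbouring tags it lay at percentile 15.2, so the list could not be told apart from such blocks.

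**Figure D2:**
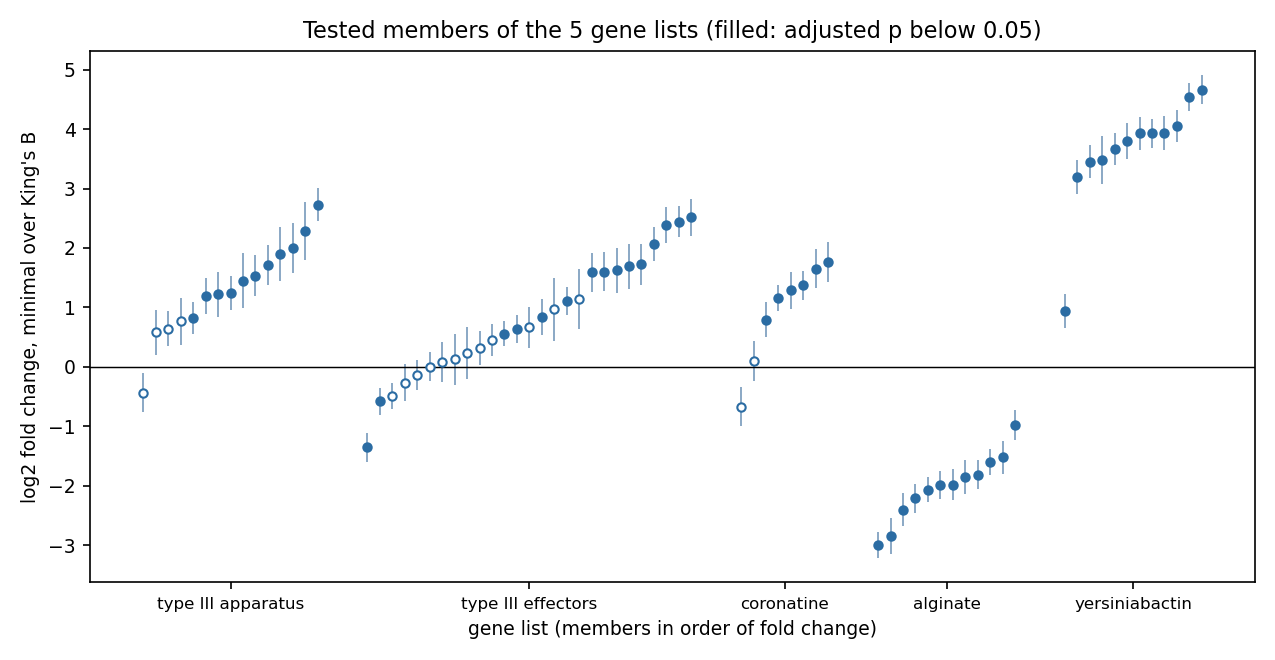
Log2 fold change, minimal over King's B, of each tested member of the 5 gene lists, with bars of 1 SE from limma-voom on 3 libraries per medium; filled points had an adjusted p below 0.05. All 12 yersiniabactin members lay above 0 and all 12 alginate members below it, while 2 of the 27 effector members fell and 13 rose. With scaling to total counts, the median of the effector list was -0.14.

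The type III secretion apparatus, which delivers effector proteins into plant cells, and its regulators were listed as 25 tags between PSPTO_1379 and PSPTO_1404. Only 15 passed the filter on reads, which counts reads on r tags in the library size. Of these, 11 rose, none fell and 4 did not pass the test, and 12 rose when adjusted over the list alone. Without r and t tags 20 were tested and 15 rose. With no filter on low counts 25 were tested and 16 rose. PSPTO_1381 rose 6.62-fold, from 15.0 ± 1.52 CPM in King's B to 104 ± 21.0 CPM in minimal medium (SD, n = 3 each; log2 fold change 2.73 ± 0.28, limma-voom adjusted p = 1.8e-09). PSPTO_1401 rose from 11.7 ± 2.33 to 38.6 ± 15.4 CPM (log2 fold change 1.71 ± 0.34, limma-voom adjusted p = 1.1e-04). At equal depth, PSPTO_1381 had a log2 fold change of 3.60, a value that rests on few reads (51 in King's B at full depth). PSPTO_1401 was not tested at that depth. With the replicate number as a block, 4 tags of the list were called and PSPTO_1401 was not (adjusted p = 0.066). PSPTO_1391 was the tested member with a value below 0, at -0.43 ± 0.33 (limma-voom adjusted p = 0.27). The whole list held between 186 and 740 reads per library. Its shift passed the camera test (adjusted p = 4.5e-04) and had an adjusted p = 0.20 with an estimated correlation.

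Type III effectors, with the helper proteins and chaperones that go with them, were listed as 35 tags, and 27 were tested. In minimal medium 13 rose, 2 fell and 12 did not pass, with the same counts adjusted over the list alone. PSPTO_1382 rose 5.43-fold, from 24.9 ± 9.06 to 130 ± 25.9 CPM (SD, n = 3 each; log2 fold change 2.44 ± 0.26, limma-voom adjusted p = 4.0e-09), and PSPTO_4001 rose 5.71-fold, from 13.0 ± 2.62 to 81.5 ± 24.3 CPM (log2 fold change 2.51 ± 0.32, limma-voom adjusted p = 1.1e-07). At equal depth PSPTO_4001 had a log2 fold change of 3.73, which rests on few reads (44 in King's B at full depth), and PSPTO_1382 one of 2.20. Both tags that fell carry the A of one of the plasmids in their number. PSPTOA0018 went from 89.0 ± 17.9 to 34.2 ± 1.59 CPM (log2 fold change -1.36 ± 0.25, limma-voom adjusted p = 4.3e-05), and PSPTOA0012 had a log2 fold change of -0.58 ± 0.23 (limma-voom adjusted p = 0.032). A block on the replicate number left 8 tags of the list called higher and 1 lower, PSPTOA0018. The camera test gave an adjusted p of 0.0028 for the list, and adjusted p = 0.13 with an estimated correlation. With scaling to total counts the list's median was -0.14 in log2, against 0.66 with TMM, while the median of all genes moved by a similar amount.

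Coronatine, a toxin that mimics the plant hormone jasmonoyl-isoleucine, is made from genes listed here as 17 tags, of which 8 were tested. In total 6 rose, none fell and 2 did not pass, with the same counts adjusted over the list alone. The 6 that rose all lay between PSPTO_4680 and PSPTO_4689, with a median log2 fold change of 1.33. With no filter on low counts all 17 were tested, 7 rose and 1 fell. The list's median log2 fold change was then 0.66, against 1.22 with the filter. Without r and t tags 10 were tested, 8 rose and none fell. Quantile normalization and the r-tag share as a covariate each called 1 tag lower. PSPTO_4686 rose 2.59-fold, from 129 ± 59.6 to 321 ± 70.3 CPM (SD, n = 3 each; log2 fold change 1.37 ± 0.25, limma-voom adjusted p = 3.1e-05). PSPTO_4687 rose 2.23-fold, from 131 ± 27.6 to 292 ± 55.1 CPM (log2 fold change 1.15 ± 0.21, limma-voom adjusted p = 5.0e-05). With quantile normalization their log2 fold changes were 2.47 and 2.27. With the replicate number as a block neither was called (adjusted p = 0.073 and 0.12), and 3 tags of the list were. In the second part of the list, PSPTO_4707 to PSPTO_4714, 2 of 7 tags were tested. PSPTO_4709 had a log2 fold change of 0.09 ± 0.34 and PSPTO_4710 one of -0.67 ± 0.32 (limma-voom adjusted p = 0.83 and 0.078), and the difference between the parts was not tested. The camera test gave an adjusted p of 0.017 for the list, and adjusted p = 0.20 with an estimated correlation.

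**Figure D3:**
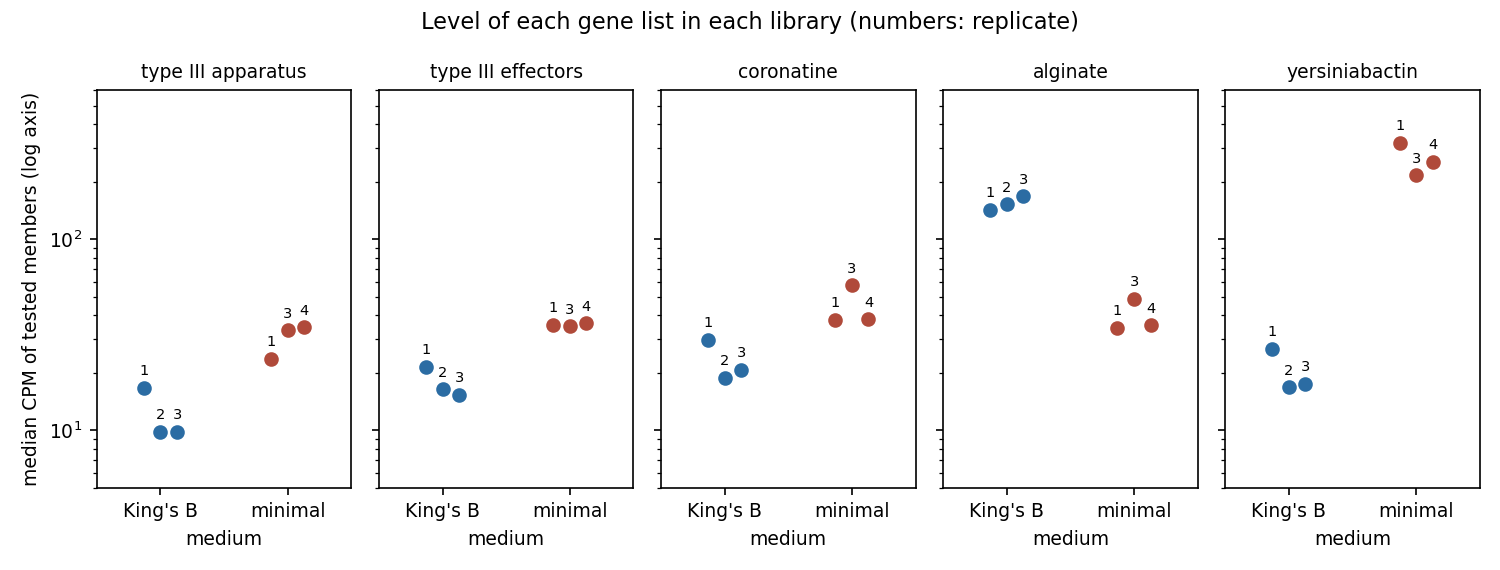
Median CPM of the tested members of each gene list in each library on a log axis, with King's B in blue, minimal medium in red and the replicate number above each point. For the type III apparatus the King's B libraries sat at 16.7, 9.84 and 9.84 CPM (replicates 1, 2 and 3) and the minimal medium libraries at 23.7, 33.3 and 34.6 CPM (replicates 1, 3 and 4).

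The libraries differed in another measure. Of the reads that fell outside r and t tags, 19.5%, 13.2% and 13.3% lay outside annotated features in King's B replicates 1, 2 and 3, and 25.4%, 35.5% and 34.0% in minimal medium replicates 1, 3 and 4. King's B replicate 1, which had the highest such share of its medium, also had the highest median level of its medium for the type III apparatus (16.7 CPM), the effectors (21.5 CPM), coronatine (29.8 CPM) and yersiniabactin (26.7 CPM), and the lowest for alginate (142 CPM). Within minimal medium the lists did not follow the share alike. Replicate 1, with the lowest share, had the lowest median for the type III apparatus (23.7 CPM) and coronatine (38.0 CPM) but the highest for yersiniabactin (319 CPM) and the lowest for alginate (34.4 CPM). Replicate 3, with the highest share, had the lowest medians for yersiniabactin (215 CPM) and the effectors (35.1 CPM) and the highest for alginate (48.7 CPM) and coronatine (57.3 CPM). With that share added to the limma-voom model as a covariate, the median log2 fold changes were 0.59 for the type III apparatus (adjusted p = 0.19), 0.50 for the effectors (adjusted p = 1.2e-04), -0.10 for coronatine (adjusted p = 0.57), -1.89 for alginate (adjusted p = 5.3e-08) and 4.48 for yersiniabactin (adjusted p = 7.0e-24). With an estimated correlation these were adjusted p = 0.78, 0.091, 0.78, 0.19 and 0.091 in the same order. Of the 27 effector tags, 6 were called in that model, against 15 without the covariate. The share separates the media, so the covariate and the medium overlap in these libraries. In that model PSPTO_4686 had a log2 fold change of -0.19 (adjusted p = 0.85), PSPTO_4687 one of 0.21 (adjusted p = 0.80), PSPTO_1401 one of 0.19 (adjusted p = 0.94) and PSPTOA0018 one of -0.65 (adjusted p = 0.54). PSPTO_1381, PSPTO_1382 and PSPTO_4001 stayed called, with larger log2 fold changes of 3.39, 3.30 and 3.71 (adjusted p = 1.2e-06, 1.3e-07 and 1.1e-06). With both libraries of lowest r-tag share left out, 2308 tags differed between media, 1203 higher and 1105 lower in minimal medium.

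Outside the lists, the tags with the furthest rise and fall could be given only by number, because no table used here pairs them with names. PSPTO_3544 rose 26.3-fold, from 16.3 ± 4.94 to 443 ± 115 CPM (SD, n = 3 each; log2 fold change 4.72 ± 0.29, limma-voom adjusted p = 5.3e-14). PSPTO_5649 had 4 reads in the 3 King's B libraries together and 202 in those of minimal medium, with a log2 fold change of 6.32 ± 1.20 (limma-voom adjusted p = 0.0062). That value was 5.59 without King's B replicate 2, 7.14 without King's B replicate 3 and 6.92 without minimal medium replicate 3, and it spanned 5.01 to 8.82 over all settings run. PSPTO_4160 was 44.6-fold higher in King's B, at 481 ± 4.99 against 10.1 ± 2.46 CPM (log2 fold change -5.48 ± 0.34, limma-voom adjusted p = 7.5e-14), and PSPTO_5466 was 34.1-fold higher there, at 1379 ± 340 against 39.5 ± 2.80 CPM (log2 fold change -5.09 ± 0.26, limma-voom adjusted p = 3.4e-15). With quantile normalization PSPTO_3544 was at 5.30 and PSPTO_5466 at -4.43.

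Tags of transfer RNA form, with a t in their number, were lower in minimal medium as a class. Of 34 tested, 32 fell, none rose and 2 did not pass, with a median log2 fold change of -2.02. With scaling to total counts 11 of them fell, with a median of -2.81. Transfer RNAs are short and structured, and libraries made from total RNA recover them poorly, so these values describe the recovered reads. None of the 10 tested r tags passed the test (lowest limma-voom adjusted p = 0.34) at a median log2 fold change of 3.48, and their share of reads spanned 0.480 to 56.2% within King's B. With scaling to total counts, 5 of the 10 r tags were called higher in minimal medium. Of the tags with the A of a plasmid in their number, 18 of 59 tested rose and 8 fell, and of those with a B, 14 of 57 rose and 6 fell. Their median log2 fold changes were 0.05 and 0.13 with TMM and -0.72 and -0.71 with scaling to total counts, where none of them was called. As a share of reads outside r and t tags, A tags held 0.605 ± 0.034% in King's B and 0.986 ± 0.055% in minimal medium. B tags held 0.592 ± 0.034% and 0.966 ± 0.036% (SD, n = 3 each, two-sided exact permutation p = 0.1 for A and for B). Tags were also put in 10 classes by mean RPM (reads scaled to those outside r and t tags), class 1 the lowest. From King's B replicates 2 and 3 to minimal medium, mean RPM rose in classes 1 to 9. In class 7 it went from 69.8 to 119, and in class 10 it fell from 1245 to 939. The raised shares alone therefore do not set plasmid tags apart from other tags.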

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

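The tests in this part were chosen after the read shares had been seen, except the tests on classes of mean expression, whose bounds were written before their values were seen. Reads that the counting placed outside annotated features, which lie outside the gene counts compared in the report, made up 31.7 ± 5.46% of reads outside r and t tags in minimal medium against 15.3 ± 3.62% in King's B (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 can give). The share was raised in every minimal medium library and, among the King's B libraries, in replicate 1 (19.5%). At an equal depth of 151765 reads outside r and t tags, the number of tags without reads was 306, 464 and 485 in King's B replicates 1, 2 and 3 and 228, 182 and 165 in minimal medium replicates 1, 3 and 4.

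For reads from ribosomal RNA loci that fall outside the r tags, the ratio of reads outside annotated features to reads on r tags was taken. It was 50.1 in King's B replicate 1. In minimal medium it was 0.157 over the 3 libraries together and 1.36 in replicate 3. A high ratio cannot exclude this source, because removal of ribosomal RNA lowers the reads on r tags and may leave other reads of those loci. This source stays open in King's B replicate 1 and in minimal medium. An even background over all genes, such as carried-over genomic DNA, predicts an excess in RPM (reads scaled to those outside r and t tags) that is about equal in neighbouring classes, when tags are put in 10 classes by mean RPM with class 1 the lowest. The excess of King's B replicate 1 over replicates 2 and 3 was 3.64 ± 0.30 RPM in class 2 and 7.94 ± 0.50 RPM in class 4 (SE over genes), a ratio of 2.18, and that of minimal medium over the same libraries was 10.7 ± 0.52 and 28.4 ± 1.16 RPM, a ratio of 2.65. These ratios lie between the bounds set beforehand for and against such a background (2 and 3), but the classes were set by means that include the excess; with classes set by King's B replicate 2 and the excess taken over replicate 3, a test chosen afterwards, the ratios were 1.64 and 1.91, within the bound for a background. The excess was still not even. In King's B replicate 1 it rose from 3.64 ± 0.25 RPM in class 1 to 13.9 ± 0.94 in class 7 and fell to 8.29 ± 1.12 in class 8 and -86.8 ± 18.1 in class 10; in minimal medium it rose from 13.2 ± 1.003 to 67.2 ± 5.33 in class 5 and fell to 41.8 ± 3.41 in class 8 and -435 ± 90.8 in class 10. Scaling to equal totals makes the excess sum to 0 over all classes, so a deficit in the highest classes is expected from any gain in the others. By the same sum, a fall in the highest classes would give a gain in the others. The excess alone cannot tell these apart. Without gene lengths, a background cannot be told apart from other sources. Transcription from regions that the annotation leaves out in minimal medium was not tested and stays open too, although the medium alone cannot account for King's B replicate 1.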

How the results depend on the processing

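limma-trend, thinning, quantile normalization, both covariates and leaving out both libraries of lowest r-tag share were chosen after seeing the data. With median-of-ratios factors, either other filter, without r and t tags, without the 10 most abundant tags, limma-trend, quantile normalization, both libraries of lowest r-tag share left out, the r-tag share as a covariate and an adjusted p of 0.01, each count of changed tags stayed within 1.5 times its value, and all 5 lists passed where lists were tested with camera's preset correlation; camera with an estimated correlation passed 0 lists, where fry passed 5. Without each library in turn, 1954 to 2805 tags changed (939 to 1426 higher, 1015 to 1379 lower, 1577 to 2097 over 2-fold) and 5 lists passed; the lowest count, 1954, was without minimal medium replicate 3, and its cause was not tested. The filter on reads left 27 of the 101 listed tags untested. With no filter on low counts the coronatine median was 0.66 in log2, against 1.22 with it, and 1 tag of that list was called lower.

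Scaling to total counts moved all 15 named tags by over 1.5 times, the share of reads outside features as a covariate 12 and quantile normalization 6 (PSPTO_1243 to -1.60, PSPTO_1232 to -0.9998, PSPTO_4686 to 2.47, PSPTO_4687 to 2.27). Quantile normalization also called 11 of the 2592 changed tags in the other direction. Scaling to total counts gave 270 changed tags (20 higher, 250 lower, 270 over 2-fold) and a median of -0.14 for the effector list, with PSPTO_2602 at 3.72 (4.53 with TMM) and PSPTO_4160 at -6.31 (-5.48 with TMM); its construction leaves the r reads in the scale. Thinning to 151765 reads gave 1637 changed and 757 higher, with 3204 tags tested and r and t tags left out as well. Testing against a 2-fold change gave 569 tags, since it asks that the change exceed the threshold beyond its error. With the share of reads outside features as a covariate, 533 tags changed (207 higher, 326 lower, 524 over 2-fold), 3 lists passed, the coronatine median was -0.10 and PSPTO_4686 was at -0.19; the covariate overlaps with the medium, and the cause was not tested.

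The media share the numbers 1 and 3 only. With the number as a replicate block, 1027 tags changed (363 higher, 664 lower, 1027 over 2-fold) and 5 lists passed, with 1 residual degree of freedom; PSPTO_1401 (1.37, adjusted p = 0.066), PSPTO_4686 (1.16, adjusted p = 0.073) and PSPTO_4687 (0.9987, adjusted p = 0.12) lost their calls, and 4 tags of the type III apparatus (11 without the block) and 3 of coronatine (6 without it) were called. In the effector list 8 tags were called higher with the block (13 without it) and 1 lower (2 without it). Deviations of same-numbered libraries correlated at -0.34 and -0.15 across genes, so the numbers were not taken to pair the samples. Among the named tags and lists, 3 of 389 values under alternatives turned, 19 kept their direction but lost the threshold, and 367 kept both. The named tags were chosen in the main fit for a small p or a large change, so this tally favours them. Of all changed tags, 10.2% kept their call with scaling to total counts and 39.4% with the replicate block. With the share of reads outside features as a covariate, 18.7% did. edgeR, DESeq2 and the list shares of counts were not run.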

Other observations

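Adjacent locus tags moved together along the chromosome. Across the 4566 tested chromosomal tags in order of their number, the log2 fold changes of neighbours correlated with r = 0.556 (across genes, which are not independent replicates), while 1000 shuffled orders reached at most 0.0437 (permutation p = 0.001, the smallest they can give). The longest stretch of adjacent tested tags that all rose held 26 tags and the longest that all fell held 44, against at most 12 and 11 in the shuffled orders.

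The tests of this pattern were chosen after it was seen. Co-transcription of neighbours in operons is a candidate explanation, since the correlation of 0.556 between neighbours fell to 0.192 at a distance of 10 tags. At 20 tags it was 0.0967, still above the 0.0437 that shuffled orders reached for adjacent tags. Operon limits were not available here, so whether operons account for the correlation at these distances was not tested. A broad gradient along the chromosome, such as a difference in gene dosage between cultures growing at different rates, would hold over long distances, and the correlation at 50 tags was 3.50% of that between neighbours. Tag numbers stand here for position, since coordinates were not used.

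For the lists with median rises under 3-fold, the bounds on random lists were written before their values were seen, but the random lists of blocks were added, and the rule tightened to need both kinds, after the percentiles for single tags were known; the tests with a covariate were chosen afterwards too. Because tags of low abundance held a higher share of reads in minimal medium, each list was set against 10000 random lists of the same size matched on mean expression, whose medians centred on 0.25, 0.09 and 0.04 for the type III apparatus, effectors and coronatine. The lists' own medians of 1.24, 0.66 and 1.22 lay at percentile 99.98 for the type III apparatus, 98.84 for the effectors and 99.24 for coronatine, while camera with an estimated correlation gave adjusted p = 0.20, 0.13 and 0.20. Random lists of single tags ignore that neighbours move together. Among 10000 random lists made of equally long blocks of neighbouring tags, the medians lay at percentile 91.23, 95.56 and 97.48, within the central 95%. Those block lists centred on 0.40, 0.12 and -0.16 in the same order, below the lists' own medians. For coronatine the matched blocks thus showed no general rise at their centre. The spread of the block lists is wide, so the 3 lists cannot be told apart from other blocks of neighbours of like abundance. How much a general rise of low-abundance tags adds to each list stays open within that spread, and blocks of regulated genes are among those drawn. Among such blocks the yersiniabactin median lay at percentile 100 and the alginate median at 15.2, the latter within the central 95%. The blocks matched to alginate centred on -1.0007, with a central 95% from -3.16 to 0.94, against the list's own median of -1.99. By these draws the alginate list cannot be told apart from other blocks of neighbours of like abundance either. Those draws repeat few windows that overlap each other (256 for these 2 lists, 1360 for the type III apparatus, and as few as 377 and 1259 for a block of the effectors and coronatine), so these percentiles are rough. With the share of reads outside annotated features as a covariate, the median log2 fold changes were 0.593 for the type III apparatus (adjusted p = 0.19), 0.504 for the effectors (adjusted p = 1.2e-04, and adjusted p = 0.091 with an estimated correlation) and -0.097 for coronatine (adjusted p = 0.57). For all 3 lists a factor that follows that share and the medium cannot be told apart, because no library of one medium has a share within the range of the other, and a response of these genes to the medium stays open as a hypothesis.

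Whether other groupings of the 6 libraries would give as many changed tags was checked on all 10 splits. The real split called 2592 tags and the highest of the other splits called 0, but 10 splits are too few for a share under 0.05. The next 2 tests were chosen after the data had been seen. With the r-tag share of each library as a covariate, whose ranges in the media overlap, 95.6% of the 2560 changed tags outside the r and t classes were still called in the same direction, at a median of 1.09 times the log2 fold change without it, which argues against reads on r tags as the whole cause. At equal depth 62.4% of the 2560 were still called in the same direction, under a bound of 75% that was first set for all of them; the bound was then applied to the 2067 tags that could be tested there, after both shares were known, and 77.3% of these kept their call (76.7 to 81.6% in 20 further thinnings). Log2 fold changes of the tested tags were as a median 0.963 times those at full depth. Thinning draws at random from the same reads and keeps fold changes on average, so this ratio decides nothing about depth. The calls that were kept show only that those tags could be called without unequal depth. The 469 tested tags that lost their call had a median absolute log2 fold change of 0.85 with a median SE of 0.28 at full depth, and of 0.69 with 0.38 at equal depth, so their calls ended with a smaller change and a larger error. For the 493 tags with too few reads to test, unequal depth cannot be told apart from a response to the medium.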
